A study of Mus musculus with 6 samples.

How the data were processed

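Total RNA of mouse spinal cord was extracted with TRIzol and sequenced as 150 bp paired-end reads on an Illumina NovaSeq, per the labels' protocols. The 6 libraries form 2 groups of 3, cord of injured mice with and without rotarod training. The labels do not say whether each library came from a separate mouse, and p-values then measure only the spread between these samples, which may be technical.

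The authors deposited 1 table of raw read counts per Ensembl gene, with no normalization, alongside gene symbols, coordinates, lengths and biotypes. The submitters' processing notes name Bowtie 0.12.2 and the builds mm8 and mm9 with no role given, and the read counter, annotation release and use of strand are not given in the sources used here. The coordinates in the table were compared with the GENCODE M21 annotation of GRCm38: 54495 of 54532 gene IDs were found there, and 53585 of these (98.3%) had the same chromosome, start and end. Coordinates are given as the table prints them, with 1-based positions. Because reads may have been counted without strand, genes that overlap others in the table cannot be told apart from them in full; among the genes named in the report these include Stat3, Cx3cr1, Slc2a1, Dbp, Chat and P2rx3.

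Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, quasi-likelihood fit with robust estimation, group as the only term), which kept 16909 genes; 24170 genes had no count in any library. The biological coefficient of variation was 0.122 and the median SE of a log2 fold change 0.12. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. CPM values are scaled by the TMM factors. A standard error of a log2 fold change is its size divided by the square root of the edgeR F statistic. The median log2 fold change of all genes tested was -0.0080, and RLE or upper-quartile scaling moved it to -0.0046 and 0.017.

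Cell type, pathway and response lists, 54 in all, were fixed before the data were examined, together with the tests, the alternatives and the rule for genes named in the text. Lists with at least 5 measured members were tested with limma 3.58.1 (camera, preset correlation 0.01, log2 CPM with a prior count of 2), again with an estimated correlation, and with fry. The edgeR p-values of the members were also adjusted over each list alone, with no correction across the 54 lists. Of all genes tested 10.0% had an unadjusted edgeR p below 0.05, so such calls are weaker than those over all genes. The naming rule took up to 10 genes per direction with the largest change past the test and groups that did not overlap, up to 3 members past the test from each list, the 2 members of smallest p from each list past camera with none, and 14 reference markers, 58 genes in all, some of which are not reported here. Genes named beyond that rule were chosen after their values were seen.

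The edgeR step was tested on 10 simulated data sets drawn from the means, dispersions and library sizes of these libraries, with about 16673 genes each. It called 49.9% of 100 genes changed 1.5-fold and 71.4% of 100 genes changed 2-fold, and 10.3% of its calls were unchanged genes. The changed genes were all at a mean log2 CPM of at least 0. The share of unchanged genes depends on how many genes change, so it does not carry over to the 10 genes called in the deposited counts. With nothing changed it called 3.80 genes per data set on average, at a median dispersion percentile of 94.8. The 10 genes called in the deposited counts lay at a median percentile of 48.9. The simulated calls were ranked by the dispersion used to draw the counts. The real calls were ranked by a dispersion estimated from the same counts that gave the calls. A call favours a low estimate, so the percentiles do not show that the 10 calls differ from false ones. On a simulated set with 1 list raised 1.3-fold, camera gave that list an adjusted p of 3.21e-16 and called 0 others. Genes were drawn independently there, so the simulation does not test camera's preset correlation where the members of a list vary together.

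Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 1 CPM in 3 libraries, a replicate block, other thresholds and leaving out each library, and, chosen after seeing the data, the mean of the Schwann cell or phagocytic microglia list as a covariate. All 6 libraries had 0 counts for the Y-linked genes checked and 401 to 522 CPM of Xist, the pattern of female mice.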

Results

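RNA was sequenced from the spinal cord of C57BL/6J mice with a spinal cord injury, of which 3 libraries came from mice trained on the rotarod, a rotating rod on which a mouse must keep walking, and 3 from mice without training. The labels place all 6 libraries at day 28, counted from training. The table held raw read counts for 54532 genes, with total counts of 26092014, 16254344 and 15814104 in trained replicates 1, 2 and 3 and of 18081949, 16763602 and 15947347 in untrained replicates 1, 2 and 3. At these depths 3 counts, the floor used for an undetected gene, correspond to 0.115 to 0.190 CPM (read counts scaled to the size of the library). The comparison asked how the expression profile of the injured cord differed between mice with and without rotarod training.

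Between trained and untrained spinal cord 10 of 16909 genes passed the test, 1 higher and 9 lower in trained cord. The highest count in any other split of these libraries into 3 and 3 was 9. Arc, a neuronal activity-regulated gene of the postsynapse, rose 1.69-fold, from 21.8 ± 1.91 to 36.8 ± 2.97 CPM (mean ± SD, n = 3 per group). Dusp1, a phosphatase that inactivates MAP kinases, fell from 66.1 ± 10.1 to 24.6 ± 1.05 CPM, and Btg2, an antiproliferative early-response gene, from 37.4 ± 3.93 to 14.4 ± 1.54 CPM. Zbtb16, a transcription factor gene induced by glucocorticoids, fell from 16.3 ± 1.61 to 6.51 ± 0.189 CPM.

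The other genes that fell were Apold1, Klf4, mt-Tl1, Sik1, Id1 and Usp53. Apold1, an early-response gene of endothelial cells, had the largest change, 8.37-fold lower, from 54.7 ± 16.2 to 6.58 ± 0.916 CPM. Klf4, a zinc-finger transcription factor gene, was 2.71-fold lower, at 9.96 ± 1.20 CPM in trained and 26.8 ± 6.51 CPM in untrained cord. Sik1, a salt-inducible kinase gene, was 1.97-fold lower, and Id1, an inhibitor of helix-loop-helix transcription factors and a target of BMP signalling, 1.89-fold lower. Usp53, of the ubiquitin-specific protease family, was 1.55-fold lower. The mitochondrial leucine tRNA mt-Tl1 was 2.20-fold lower, at 7.12 ± 0.601 against 15.6 ± 0.787 CPM. It is a gene of 75 bp between other mitochondrial genes, and its counts are uncertain because 150 bp reads reach into its neighbours. In each of the 10 genes every trained library lay on the same side of every untrained one.

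In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold changes (trained over untrained) were -1.43 ± 0.11 (SE) for Dusp1 and -1.38 ± 0.11 for Btg2, both with an adjusted p of 0.000149. They were -1.32 ± 0.13 for Zbtb16 (adjusted p = 0.00141 in edgeR) and -1.14 ± 0.13 for mt-Tl1 (adjusted p = 0.00504 in edgeR). Arc at 0.76 ± 0.10, Klf4 at -1.44 ± 0.17 and Sik1 at -0.98 ± 0.13 shared an edgeR adjusted p of 0.00968. Id1 at -0.92 ± 0.13 had an edgeR adjusted p of 0.0308, and Apold1 at -3.07 ± 0.26 and Usp53 at -0.63 ± 0.10 had 0.0471. At an unadjusted p below 0.05, 1693 genes differed, 755 higher and 938 lower. In 2843 genes (16.8%) the groups did not overlap, against 10% on average over all splits of the libraries into 3 and 3. Genes vary together between libraries, so a single split can depart from that average, and the share in the other splits was not computed. Without trained replicate 2, 4 genes passed (Btg2, Dusp1, mt-Tl1 and Zbtb16), and Arc, Klf4 and Sik1 had an edgeR adjusted p of 0.119. Without trained replicate 3, 221 genes passed, 73 higher and 148 lower, 9 of the 10 among them, and without trained replicate 1, 21 passed, 13 higher and 8 lower, 8 of the 10 among them. Apold1 lost its call without trained replicate 1, 2 or 3 or untrained replicate 2 (edgeR adjusted p = 0.191, 0.321, 0.0747 and 0.231), and Id1 without trained replicate 2 or untrained replicate 2 (0.197 and 0.231). Usp53 lost it without trained replicate 1 or 2 or untrained replicate 1, 2 or 3 (0.0502, 0.171, 0.114, 0.241 and 0.167), so its call held in 1 of these 6 fits.

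**Figure D1:**
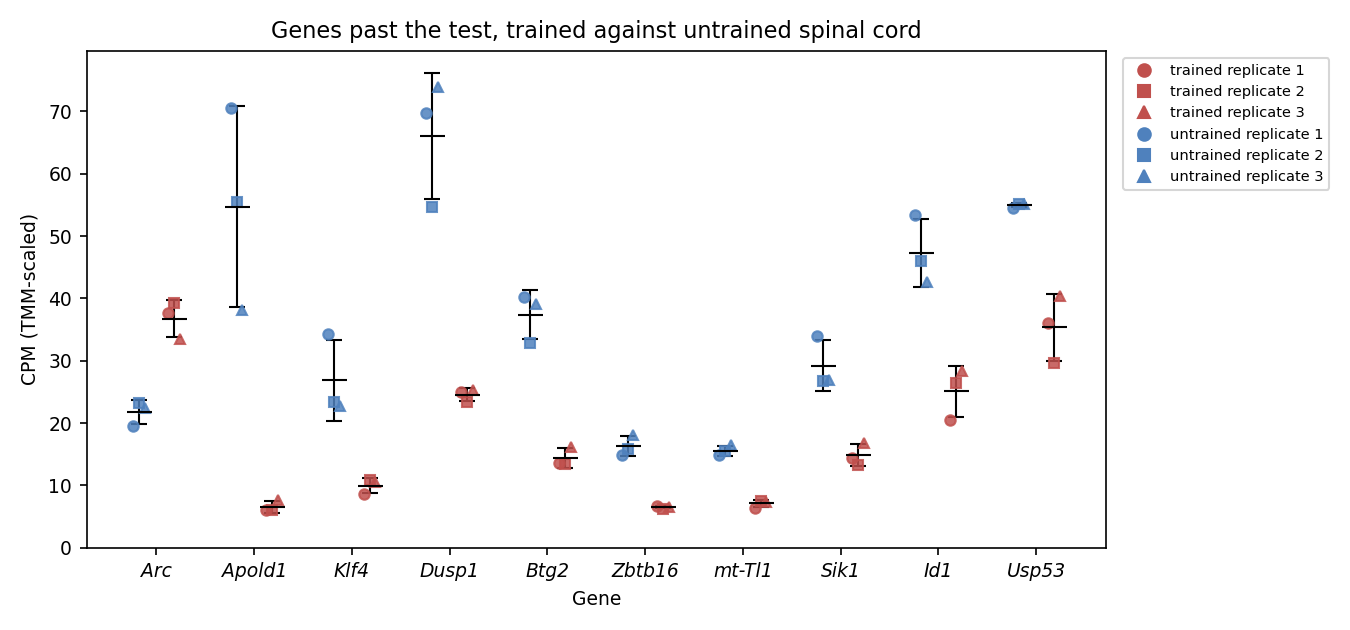
CPM (TMM-scaled, y axis) of the 10 genes past the test in each of the 6 libraries (points; shape gives the replicate number), with the group mean and SD of 3 libraries as black bars. Arc lies higher in the 3 trained libraries (mean 36.8 against 21.8 CPM) and the other 9 genes lie lower, Dusp1 at 24.6 against 66.1 CPM.

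Positions of the 10 genes are those the deposited table gives. Arc (ENSMUSG00000022602) spans bases 74669083 to 74672570 of chromosome 15. Dusp1 (ENSMUSG00000024190) spans 26505590 to 26508519 and Sik1 (ENSMUSG00000024042) 31844248 to 31855792 of chromosome 17. Btg2 (ENSMUSG00000020423) lies at 134075170 to 134079120 of chromosome 1 and Zbtb16 (ENSMUSG00000066687) at 48654297 to 48836222 of chromosome 9. Klf4 (ENSMUSG00000003032) lies at 55527143 to 55532466 of chromosome 4, Apold1 (ENSMUSG00000090698) at 134981718 to 134986836 of chromosome 6 and Id1 (ENSMUSG00000042745) at 152736251 to 152737410 of chromosome 2. Usp53 (ENSMUSG00000039701) spans 122931493 to 122984510 of chromosome 3, and mt-Tl1 (ENSMUSG00000064340) bases 2676 to 2750 of the mitochondrial genome. No other gene of the table overlaps any of the 10, and 8 of them have the same ends in the GRCm38 annotation (all but Dusp1 and Sik1).

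Among the activity-dependent immediate early genes, which neurons and other cells transcribe within minutes of a stimulus, 1 of 16 measured members rose (Arc), 2 fell (Dusp1 and Btg2) and 13 did not pass over all genes tested. Adjusted over the list alone, 10 fell (Btg2, Dusp1, Egr1, Fos, Fosb, Fosl2, Ier2, Junb, Nr4a1 and Nr4a3) and 2 rose (Arc and Npas4). Nr4a1, an orphan nuclear receptor gene, was at 16.3 ± 2.23 CPM in trained and 45.2 ± 11.4 CPM in untrained cord, and Fos was at 22.6 ± 4.17 and 30.4 ± 4.33 CPM. Nr4a1 passed over all genes in edgeR without untrained replicate 1 or 3 (adjusted p = 0.00656 and 0.000580), and Fosl2 without untrained replicate 3 (0.00145). Npas4, a neuronal transcription factor gene that depends on calcium influx, was at 2.31 ± 0.701 and 1.21 ± 0.459 CPM. The list had a median log2 fold change of -0.41 (limma camera adjusted p = 0.000352). With an estimated correlation its camera adjusted p was 0.738.

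The glucocorticoid response list, genes that corticosterone induces or represses in many tissues, was also lower, with a median log2 fold change of -0.29 over 14 members (limma camera adjusted p = 3.16e-06, and adjusted p = 0.694 with an estimated correlation). Over all genes tested 1 member fell (Zbtb16) and 13 did not pass. Adjusted over the list alone, 7 fell and 0 rose: Errfi1, Fkbp5, Klf9, Nr3c1, Per1, Sgk1 and Zbtb16. Sgk1, a serum- and glucocorticoid-induced kinase gene, was at 78.2 ± 9.87 CPM in trained and 185 ± 52.5 CPM in untrained cord, while the metallothionein gene Mt1 had a log2 fold change of 0.0048. Sgk1 passed over all genes in edgeR without untrained replicate 1 (adjusted p = 0.00253), and Per1 without untrained replicate 3 (0.0411). The circadian clock list, which shares Per1 with it, was lower too, with a median of -0.16 over 15 members (limma camera adjusted p = 0.0111, and 0.738 as the adjusted p with an estimated correlation). No member passed over all genes, and adjusted over the list alone Per1 fell (log2 fold change -0.54 ± 0.13) and Dbp, an output gene of the clock, rose (0.28 ± 0.09). Its call was lost without trained replicate 1 (camera adjusted p = 0.0565).

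Neutrophil genes were higher in trained cord, with a median log2 fold change of 1.46 over 9 measured members (limma camera adjusted p = 3.84e-06, and adjusted p = 0.800 with an estimated correlation). None of the 9 passed over all genes tested in the main edgeR fit (filterByExpr, group as the only term, all libraries). Adjusted over the list alone 7 rose (Camp, Elane, Ltf, Ngp, Retnlg, S100a8 and S100a9) and 0 fell. Over all genes DESeq2 called Camp, Ngp, S100a8 and S100a9 (adjusted p = 0.0276, 0.000458, 0.000699 and 6.0e-06), and edgeR without trained replicate 1 called Camp, Ngp and S100a9 (adjusted p = 0.0290, 0.00356 and 0.000162). S100a9, a subunit of the granulocyte protein calprotectin, was at 15.5 ± 5.55 CPM in trained and 5.58 ± 0.557 CPM in untrained cord. The granule protein gene Ngp was at 9.83 ± 3.58 against 3.53 ± 0.867 CPM, and Camp, the cathelicidin gene, had a 2.83-fold difference in the same direction. Csf3r, the receptor gene for granulocyte colony-stimulating factor, had a log2 fold change of -0.13. The red blood cell list moved with it, with a median of 0.96 over 6 members and 0 past the test over all genes or adjusted over the list alone (limma camera adjusted p = 0.00543, and 0.800 as the adjusted p with an estimated correlation). Hba-a1, an alpha-globin gene, was at 28.0, 62.6 and 70.8 CPM in trained replicates 1, 2 and 3 and at 27.4, 26.1 and 15.2 CPM in the untrained replicates. The red cell call was lost without trained replicate 2 (camera adjusted p = 0.0588).

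In 4 further lists camera gave a higher level in trained cord, and no member of any of them passed over all genes tested. All 18 cholesterol synthesis genes had positive log2 fold changes, with a median of 0.19 (limma camera adjusted p = 0.000653, and 0.800 as the adjusted p with an estimated correlation). Mvk, mevalonate kinase, was at 0.36 ± 0.11 and Dhcr7, of the last step of the pathway, at 0.33 ± 0.11, and 0 members passed adjusted over the list alone. Untrained replicate 1 had the lowest value of the 6 libraries in 14 of 18 of these genes and in 11 of 18 oligodendrocyte and myelin genes. The groups overlapped in the mean log2 CPM of the cholesterol list, centred on all libraries: trained replicates 1, 2 and 3 lay at 0.27, 0.092 and -0.074 and the untrained ones at -0.26, -0.055 and 0.029. The excitatory interneuron list had a median of 0.20 over 11 members (limma camera adjusted p = 0.00826, and adjusted p = 0.800 with an estimated correlation). Adjusted over the list alone Tac2, the neurokinin B gene, rose (log2 fold change 0.35 ± 0.10), and Tlx3, a transcription factor gene of dorsal horn neurons, was at 0.46 ± 0.16. Skeletal muscle genes had a median of 0.75 over 6 members at 0.128 to 4.10 CPM, 0 of them past adjusted over the list alone (limma camera adjusted p = 0.0200, and 0.800 as the adjusted p with an estimated correlation). Ribosomal protein genes had a median of 0.05 over 73 members, 0 past adjusted over the list alone (limma camera adjusted p = 0.0266, and 0.840 as the adjusted p with an estimated correlation), with Rpl30 at 0.46 ± 0.11 and Rpl35 at 0.25 ± 0.07. The cholesterol call was lost without trained replicate 1 or untrained replicate 1 (camera adjusted p = 0.0744 and 0.0724), the interneuron call without trained replicate 1, trained replicate 2 or untrained replicate 3 (0.0565, 0.0663 and 0.0573), the muscle call without untrained replicate 3 (0.0669), and the ribosomal call without trained replicate 3, untrained replicate 1 or untrained replicate 3 (0.263, 0.221 and 0.153). Dhcr7 was at 0.22 without trained replicate 1.

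Of the fixed glial and inflammatory lists, camera gave a lower level in trained cord for those of reactive astrocytes, phagocytic and homeostatic microglia, complement, cytokines and MHC class II. No member of these passed the test over all genes, and 1 trained library, replicate 3, did not share the fall in most of them. Those of interferon response, MHC class I, monocytes and macrophages, inflammasome, T cells, astrocytes and oligodendrocytes did not pass limma's camera (adjusted p = 0.384, 0.0725, 0.0725, 0.0935, 0.310, 0.444 and 0.203). The reactive astrocyte list had a median log2 fold change of -0.35 over 18 members, 0 of them past adjusted over the list alone (limma camera adjusted p = 0.000758, and 0.800 as the adjusted p with an estimated correlation). The intermediate filament gene Nes was at -0.33 ± 0.10 and the signalling gene Stat3 at -0.22 ± 0.08, while Gfap, the main astrocyte filament gene, was at -0.031 ± 0.12. The list of phagocytic and disease-associated microglia had a median of -0.16 over 19 members (limma camera adjusted p = 0.00432, and adjusted p = 0.800 with an estimated correlation), and adjusted over the list alone 3 fell: Clec7a, a receptor gene for fungal glucans, Cst7 and Lpl. Clec7a, annotated in the table as a polymorphic pseudogene, was at 38.3 ± 7.98 CPM in trained and 58.0 ± 4.75 CPM in untrained cord, and Lpl, lipoprotein lipase, at 57.1 ± 3.30 and 67.9 ± 3.48 CPM. Homeostatic microglia genes had a median of -0.14 over 14 members with 0 past adjusted over the list alone (limma camera adjusted p = 0.0177, and 0.800 as the adjusted p with an estimated correlation). Cx3cr1, the fractalkine receptor gene, whose span overlaps 9 other genes in the table, was at -0.32 ± 0.10. Without trained replicate 3 Clec7a and Cx3cr1 passed over all genes in edgeR (adjusted p = 0.00212 and 0.0120).

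Complement genes had a median of -0.28 over 14 members, 0 past adjusted over the list alone (limma camera adjusted p = 0.00826, and 0.800 as the adjusted p with an estimated correlation), with C3 at -0.43 ± 0.21 and its fragment's receptor gene C3ar1 at -0.41 ± 0.17. C3ar1 was at -0.25 without trained replicate 1 and -0.62 without trained replicate 3, and C3 at -0.28 without trained replicate 2 and -0.67 without trained replicate 3. Both passed over all genes in edgeR without trained replicate 3 (adjusted p = 0.0284 for C3ar1 and 0.00218 for C3). The list of cytokines, chemokines and NF-kB targets had a median of -0.38 over 18 members (limma camera adjusted p = 0.0208, and adjusted p = 0.823 with an estimated correlation). Its one member past adjusted over the list alone rose: the chemokine gene Ccl3, at 9.44 ± 2.31 CPM in trained and 4.77 ± 0.550 CPM in untrained cord. Ccl3 passed over all genes in edgeR without trained replicate 1 (adjusted p = 0.0264). The cytokine call was lost with a filter of at least 1 CPM in 3 libraries (camera adjusted p = 0.0982). Nfkbia, the NF-kB inhibitor gene, was at -0.62 ± 0.20. MHC class II presentation had a median of -0.57 over 10 members, 0 past adjusted over the list alone (limma camera adjusted p = 0.0253, and 0.800 as the adjusted p with an estimated correlation), with H2-Ab1 at 10.5 ± 5.72 against 20.5 ± 4.74 CPM and H2-DMb1 at a log2 fold change of -0.60 ± 0.19. Without trained replicate 1 the log2 fold change of H2-Ab1 was -0.60.

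The libraries of the trained group stood apart from each other in these lists. Trained replicate 1 had the lowest value of the 6 libraries in 14 of 18 reactive astrocyte, 15 of 19 phagocytic microglia and 13 of 14 complement genes, and trained replicate 3 had it in 0 of each. In mean log2 CPM, trained replicates 1 and 2 lay below every untrained library in each of these lists. Trained replicate 3 lay above every untrained library for phagocytic microglia (0.268 from the mean of all libraries, untrained at most 0.230) and complement (0.372, at most 0.367). For reactive astrocytes, homeostatic microglia and cytokines only untrained replicate 1 lay above it. Without trained replicate 1 the camera calls ended for the reactive astrocyte (adjusted p = 0.0565), phagocytic (0.188) and homeostatic microglia (0.177), complement (0.521), cytokine (0.450) and MHC class II (0.0565) lists. Leaving out trained replicate 2 ended the 2 microglia calls (0.0607 and 0.0921), and leaving out untrained replicate 1 those of homeostatic microglia (0.0835), complement (0.0701), cytokines (0.204) and MHC class II (0.202), the last also without untrained replicate 3 (0.0669). Without trained replicate 3, 34 lists passed camera in place of 19.

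Endothelial genes were lower, with negative log2 fold changes in all 14 members and a median of -0.18 (limma camera adjusted p = 0.00150, and 0.800 as the adjusted p with an estimated correlation). None passed over all genes, and adjusted over the list alone 3 fell: Flt1, a VEGF receptor gene, Pecam1, an endothelial adhesion molecule (-0.39 ± 0.11), and Slc2a1, the glucose transporter of the blood-brain barrier (-0.42 ± 0.09). The tight junction gene Cldn5 was at -0.13 ± 0.08, and at -0.064 without trained replicate 1, -0.068 without untrained replicate 1 and -0.20 without untrained replicate 3. Leaving out trained replicate 1 or untrained replicate 1 ended the endothelial call (camera adjusted p = 0.0565 and 0.0835). Motor neuron genes had a median of -0.22 over 10 members, 0 past the test over all genes or adjusted over the list alone (limma camera adjusted p = 0.0370, and 0.800 as the adjusted p with an estimated correlation). Trained replicate 3 had the lowest value in 6 of 10 of these genes, and its mean log2 CPM lay at -0.32 from the mean of all libraries, with trained replicates 1 and 2 at 0.050 and -0.11. Slc5a7, the choline transporter gene of cholinergic neurons, was at -0.47 ± 0.16, Chodl at -0.50 ± 0.18 and Chat, choline acetyltransferase, at -0.23 ± 0.14. Without trained replicate 3 Slc5a7 and Chodl were both at -0.30 and Chat at -0.074, and Chat was at -0.14 without untrained replicate 3. Without trained replicate 1 Slc5a7 was at -0.67 and passed over all genes in edgeR (adjusted p = 0.00994), and Chat was at -0.36. The motor neuron call was lost without trained replicate 2, trained replicate 3, untrained replicate 2 or untrained replicate 3 (camera adjusted p = 0.0607, 0.132, 0.0740 and 0.116).

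Genes of peripheral nerve and ganglion varied widely between libraries. Prx, the periaxin gene of Schwann cell myelin, was at 0.581 CPM in trained replicate 1, 99.7 and 48.2 CPM in trained replicates 2 and 3, and 81.4, 80.1 and 46.0 CPM in the untrained replicates. The Schwann cell list had a median log2 fold change of -0.45 over 11 members, 0 past the test over all genes or adjusted over the list alone (limma camera adjusted p = 0.0177, and 0.800 as the adjusted p with an estimated correlation), with Erbb3 at -0.17 ± 0.09 and Cdh19 at -0.26 ± 0.15. Without trained replicate 1 Erbb3 was at -0.11, Cdh19 at -0.096 and Prx, at -0.51 with all libraries, at 0.094, and without untrained replicate 2 Cdh19 was at -0.17. The list's call ended without trained replicate 1 (camera adjusted p = 0.798), untrained replicate 1 (0.0571) or untrained replicate 2 (0.0725). The dorsal root ganglion list had a median of -1.21 over 10 members, 0 past the test either way (limma camera adjusted p = 0.0217, and 0.800 as the adjusted p with an estimated correlation), with the ATP receptor gene P2rx3 at -0.58 ± 0.37. The ganglion sodium channel gene Scn10a was at 9.19, 3.32 and 3.48 CPM in untrained replicates 2 and 3 and trained replicate 3, and at 0, 0 and 0.124 CPM in untrained replicate 1 and trained replicates 1 and 2, the last 3 at or under the floor of 3 counts. P2rx3 was at -0.31 without trained replicate 3 and -0.29 without untrained replicate 2. The ganglion call was lost without trained replicate 1, trained replicate 2, untrained replicate 2 or untrained replicate 3 (camera adjusted p = 0.0744, 0.1002, 0.379 and 0.0669).

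**Figure D2:**
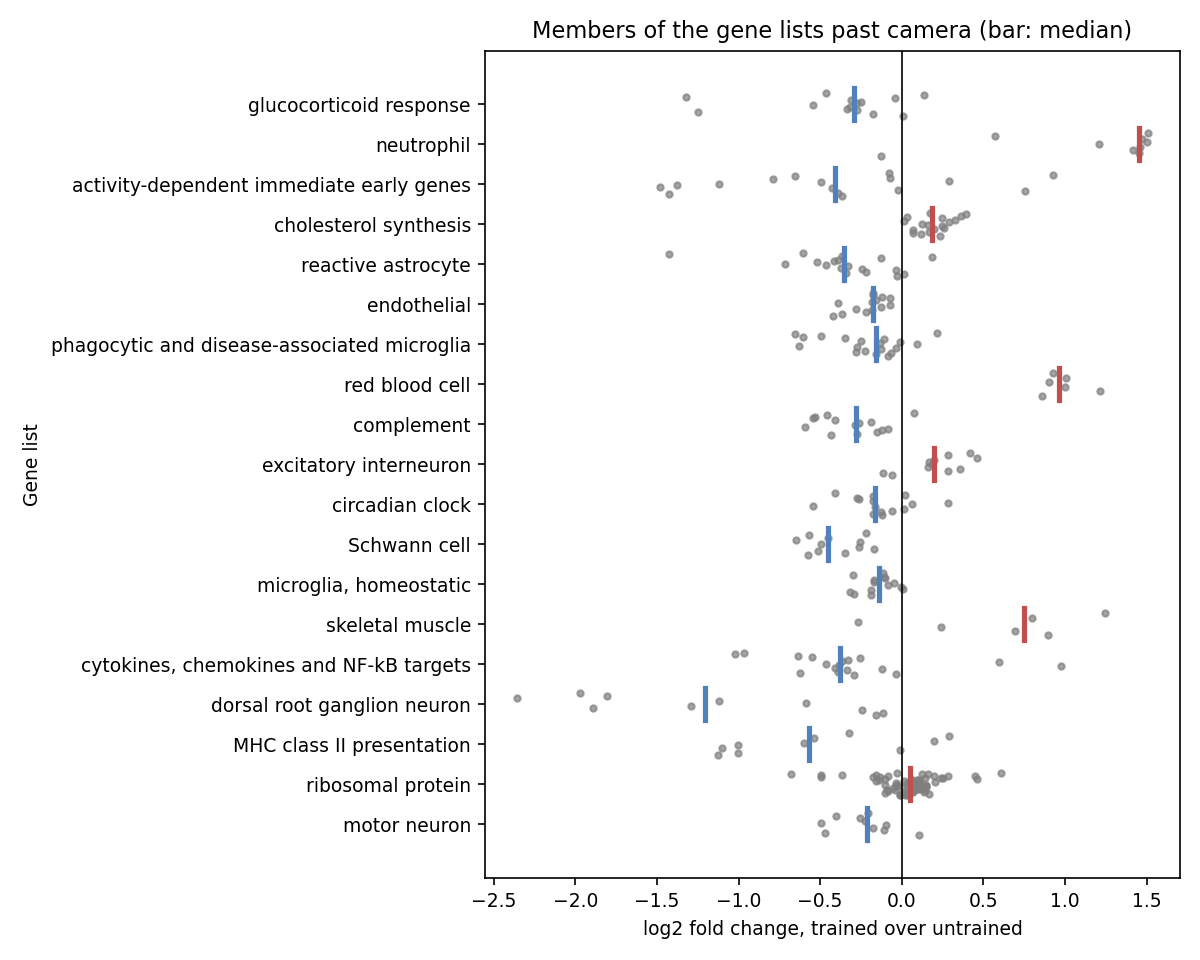
Log2 fold change, trained over untrained (x axis), of each measured member (grey points) of the 19 gene lists past camera (y axis), with the list's median as a bar, red where camera gave a higher and blue where it gave a lower level. The neutrophil median lies at 1.46 and the dorsal root ganglion median at -1.21, and the other medians lie between them.

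Across the 54 lists, 19 passed limma's camera at the preset correlation of 0.01, 6 higher and 13 lower in trained cord, and 0 passed with an estimated correlation or with limma's fry, where the lowest adjusted p-values were 0.694 and 0.0942. At an unadjusted p below 0.05 there were 3 lists with an estimated correlation (glucocorticoid response, circadian clock and immediate early genes) and 5 with fry (these 3, neutrophil and neurotrophic factors). In fry's test for change in either direction 7 lists passed, the glucocorticoid, clock and immediate early gene lists among them (adjusted p = 1.53e-05, 0.00100 and 0.00389). Without trained replicate 1, 9 lists passed camera, without trained replicate 3, 34, and without untrained replicate 1, 11. The glucocorticoid, neutrophil and immediate early gene lists were the 3 that kept their camera call in each of the 6 fits that left out a library.

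**Figure D3:**
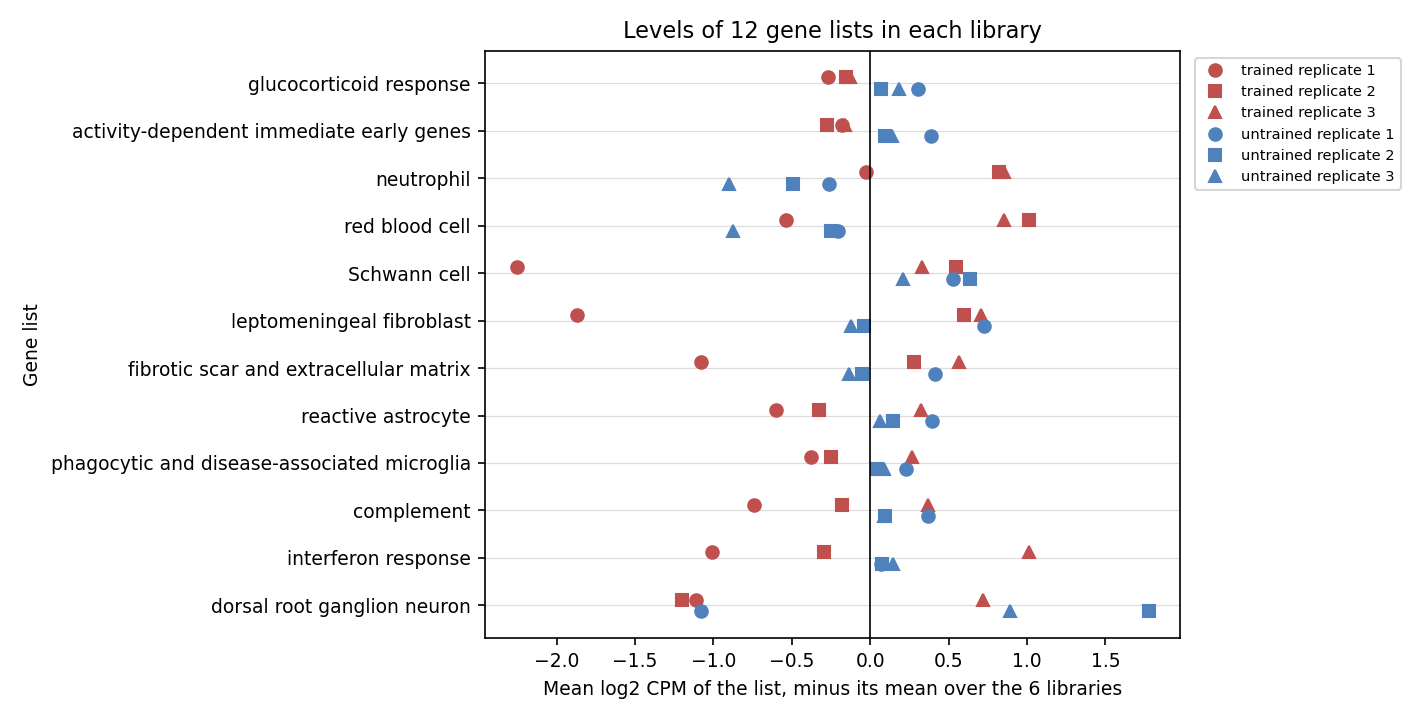
Mean log2 CPM of 12 gene lists (y axis) in each library, minus the list's mean over the 6 libraries (x axis); color gives the group and shape the replicate number. The trained libraries lie below the untrained ones for glucocorticoid response genes and above them for neutrophil genes, and trained replicate 1 lies at -2.25 for Schwann cell genes.

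The other 35 lists did not pass camera, and in 8 of them the median, the mean and the direction of camera differed in sign, the general neuron and synaptic vesicle lists among them. Id1 fell over all genes in the list of WNT, TGF-beta and Notch signalling, where Hes1, Id1 and Tgfbr1 fell adjusted over the list alone and the median was -0.11 (limma camera adjusted p = 0.0556). Snap25, of synaptic vesicle fusion, had a log2 fold change of -0.0083 ± 0.095, and the medians of the general neuron, synaptic vesicle and glutamate receptor lists were -0.0046, -0.0057 and 0.015. Trained replicate 3 had the lowest value of the 6 libraries in 8 of 16 general neuron, 13 of 20 synaptic vesicle, 11 of 16 glutamate receptor and 12 of 17 GABA and glycine receptor genes, and its mean log2 CPM lay at -0.14 from the mean of all libraries for the general neuron list, with trained replicates 1 and 2 at 0.072 and 0.059. The myelin gene Mbp was at 0.18 ± 0.09, and the oligodendrocyte list had a median of 0.025. Aqp4, the astrocyte water channel gene, was at -0.16 ± 0.11, the microglial genes Aif1 and P2ry12 at -0.30 ± 0.18 and -0.05 ± 0.09, the lysosomal gene Cd68 at -0.11 ± 0.35 and the leukocyte gene Ptprc at -0.38 ± 0.22. Collagen gene Col1a1 was at 0.34 ± 0.80, the neurotrophin gene Bdnf at 0.09 ± 0.18 and the growth cone gene Gap43 at 0.18 ± 0.07. None of these reference genes passed in the main edgeR fit with all 6 libraries. Over the fits that left out a library, Aqp4 ranged from -0.27 to -0.073, Aif1 from -0.49 to -0.16, Cd68 from -0.45 to 0.11, Ptprc from -0.63 to -0.23 and Col1a1 from -0.047 to 0.81, each lowest without trained replicate 3, where Ptprc passed in edgeR (adjusted p = 0.0200). Snap25 changed sign with upper-quartile scaling (0.016).

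Pearson correlations of log2 CPM across genes averaged 0.986 within and 0.985 between groups, and the first principal component (32.6% of the variance) set trained replicate 1 apart at -40.2, with trained replicate 2 at -9.37, trained replicate 3 at 21.7 and the untrained libraries at 3.73 to 14.4. Counts of every pair in a group differed by more than sampling noise (chi-square per degree of freedom of 5.89 to 19.8).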

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

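The covariates from gene list means were chosen after seeing the data; the other alternatives were planned. Dusp1, Btg2, Zbtb16 and mt-Tl1 passed in all 15 alternative fits, Sik1 in 14, Arc and Klf4 in 13, Id1 in 11 and Apold1 and Usp53 in 6, and none of the 10 changed direction in any of them. Their edgeR, DESeq2 or voom adjusted p-values reached at most 0.00520 for Dusp1 and Btg2, 0.0242 for Zbtb16, 0.0420 for mt-Tl1, 0.119 for Arc and Sik1, 0.135 for Klf4, 0.351 for Id1, 0.321 for Apold1 and 0.241 for Usp53. Against 10 genes (1 higher, 9 lower), RLE scaling gave 9, upper-quartile scaling 7, a filter of 1 CPM in 3 libraries 9 and limma-voom 12.

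With no filter on low counts 276 genes passed (119 higher, 157 lower) and with DESeq2 86 (35 higher, 51 lower), the 10 among them each time. With the replicate number as a block in edgeR 5 passed (0 higher, 5 lower: Btg2, Dusp1, Sik1, Zbtb16 and mt-Tl1), and Apold1, Arc, Id1, Klf4 and Usp53 were lost. The labels do not say whether the number pairs libraries across the groups. Deviations from the group mean correlated at -0.182, -0.0906 and -0.126 between libraries of the same number. These values show no pairing but cannot exclude it. An added limit of 1 on the absolute log2 fold change left 6 (0 higher, 6 lower), the same limit at an unadjusted p below 0.05 gave 107 (41 higher, 66 lower), and an adjusted p below 0.1 gave 18 (4 higher, 14 lower). With the Schwann cell list mean as a covariate 20 genes passed (11 higher, 9 lower), 9 of the 10 among them, and with the phagocytic microglia list mean 99 (24 higher, 75 lower), 9 of the 10 among them. Leaving out 1 library gave from 4 genes (0 higher, 4 lower, without trained replicate 2) to 221 (73 higher, 148 lower, without trained replicate 3), and from 9 lists (without trained replicate 1) to 34 (without trained replicate 3). Camera called 19 lists with RLE scaling, 18 with the CPM filter, which ended the call of cytokines, chemokines and NF-kB targets (adjusted p = 0.0982), and 20 with the block, which ended that of the ribosomal protein list (0.0658) and added MHC class I presentation and inflammasome, and 0 lists passed with an estimated correlation or fry. The added limit on the fold change lowers counts by construction, and for the other changes the cause was not tested.

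Among named genes with no call, DESeq2 also called Camp, Ccl3, Clec7a, Fosl2, Hapln2, Klf6, Nfkbia, Ngp, Nr4a1, Per1, Rpl30, S100a8, S100a9, Sgk1 and Slc2a1, and limma-voom Nr4a1 and Sgk1. With no filter on low counts edgeR also called named genes, C1ql1, Camp and Ccl3 among them. Other genes with no call changed sign. With upper-quartile scaling Snap25 had a log2 fold change of 0.016, and with no filter 0.0019. With the Schwann cell covariate Cd68 was at 0.10 and Prx at 0.12, and with the microglia covariate Cd68 was at 0.25, Csf3r at 0.12 and Gfap at 0.089. Mt1 was at -0.011 with limma-voom and -0.014 with the block. Over the fits that left out a library the range was -0.057 to 0.10 for Snap25, -0.15 to 0.089 for Gfap, -0.45 to 0.11 for Cd68, -0.047 to 0.81 for Col1a1, -0.052 to 0.22 for Bdnf, -1.57 to 0.094 for Prx, -0.35 to 0.0071 for Csf3r and -0.15 to 0.12 for Mt1, and the cause was not tested. Alternatives on FPKM or TPM values were not run, because the table holds counts. Depth limits what can be said of genes near the floor of 3 counts, such as Scn10a.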

Other observations

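The counts over the other splits of the libraries were planned, and the tests on gene groups, tissue content, blood and marrow in this part were chosen after the results they bear on were seen. In limma's fry test for change in either direction, adjusted over the 54 lists, the list of proteoglycans and the perineuronal net had an adjusted p of 0.00100. Adjusted over the list alone Hapln2, a link protein gene of the node of Ranvier, rose from 159 ± 12.98 to 201 ± 11.7 CPM, and Tnr, the tenascin-R gene, fell from 166 ± 11.2 to 132 ± 10.7 CPM (mean ± SD, n = 3 per group). Over all genes neither passed in the main edgeR fit (filterByExpr, group as the only term, all libraries), and Hapln2 did in edgeR without trained replicate 3 (adjusted p = 0.0432). The astrocyte list had an adjusted p of 0.00189 in the same limma test, with 0 members past in the main edgeR fit over all genes or adjusted over the list alone. The glutamate transporter genes Slc1a2 and Slc1a3 and the bicarbonate transporter gene Slc4a4 had log2 fold changes of -0.19, -0.18 and -0.21. Aldoc, a glycolytic enzyme gene, Agt, the angiotensinogen gene, and Aldh1l1, of folate metabolism, were at 0.19, 0.22 and 0.17.

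Regeneration-associated genes had a limma fry adjusted p of 0.0334 for either direction. Adjusted over the list alone 3 rose: the growth cone genes Gap43 and Basp1 (log2 fold changes 0.18 and 0.19) and Vgf, a neuropeptide precursor gene (0.29). The 3 that fell were transcription factor genes, Jun at -0.31, Klf6 at -0.52 and Stat3 at -0.22. None of the 6 passed over all genes in the main edgeR fit with all libraries, and in edgeR without trained replicate 3 Jun and Klf6 did (adjusted p = 0.0415 and 0.0184). In the oligodendrocyte precursor list (adjusted p = 0.0437 in the same limma test) C1ql1, a complement-like secreted protein gene, rose adjusted over the list alone (0.39).

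Dusp1, Btg2, Apold1, Klf4, Zbtb16, Sik1, Id1, Usp53 and mt-Tl1 fell while Arc rose. A smaller share of endothelial cells would lower the 14 endothelial genes too, and all 14 had negative log2 fold changes. Their median was -0.18 (SD 0.11), against a smallest fall of -0.63 among the 9 genes. The 9 were picked for passing the test, so a larger fall than in a list not so picked was likely in advance. The comparison therefore does not decide on a smaller endothelial share, which stays open. Without trained replicate 1 the median of the 9 genes was -1.34, against -1.32 with it, so that library alone did not carry their fall. The 9 genes were called in these same libraries, and in each the groups did not overlap. A median that stayed low was thus likely in advance, and it does not decide on the tissue content of that library. A general induction of immediate early genes in untrained tissue at collection would lower Arc in trained cord and leaves its rise, at 0.76, unaccounted for, which restates part of the pattern. For the 9 lower genes it cannot be told apart from an effect of training, which stays open: the other 13 immediate early genes had a median of -0.39, and the labels do not give handling at collection.

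Schwann cell genes were near 0 in trained replicate 1, with Prx, the periaxin gene, at 0.581 CPM against 46.0 to 99.7 CPM elsewhere. This library also had the lowest value in 12 of 12 leptomeningeal genes, which is consistent with a tissue piece with fewer nerve roots and less meninges. It had the lowest value in 14 of 18 reactive astrocyte genes, which is consistent with a piece with less of the injured tissue. Scar fibroblasts share genes with the meninges and no uninjured library was used here, so both stay open, and no biological explanation was tested.

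Neutrophil genes were higher in trained cord, by a median of 1.46 (median SE 0.37). With the red blood cell list mean as a covariate the median was 0.73 (median SE 0.33), so the difference became smaller and some of it remained. That SE is of single genes, not of the median, and the covariate is itself measured with error. The fit therefore leaves residual blood open, for part or for the whole. Fragments of bone marrow cannot be told apart from a difference in the cord: 16 genes of immature marrow cells summed to 8.62 ± 2.61 CPM in trained and 4.54 ± 0.577 CPM in untrained libraries, but the gap between the closest libraries of the groups, 0.503 CPM, was under its counting error of 0.710 CPM. More neutrophils in the cord of trained mice stay open, untested.

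The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 10 genes and the highest other 9 (trained replicates 1 and 2 with untrained replicate 1 against the rest), and 1 split, the real one, reached 10. Which side of another split counts as trained is arbitrary, so its larger count in either direction was compared with the real one. For genes higher the real split gave 1 and the highest other 9, with 3 splits as large, and for genes lower 9 and 9, with 2 as large. For lists the real split gave 19 and the highest other 32, with 5 as large; that split set trained replicates 1 and 2 with untrained replicate 2.

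Hox genes, which mark position along the cord, were chosen after their values were seen, and no test compared their paralogue groups. None of 28 passed in edgeR (lowest adjusted p 0.218), 9 had an unadjusted p below 0.05, 1 passed in DESeq2, 4 with no filter on low counts and 3 in edgeR without trained replicate 3. The level was higher in trained cord in 6 of 7 genes of groups 1 to 3 and in 15 of 18 of groups 4 to 9 (median log2 fold change 0.18), and lower in 3 of 3 of group 10. These counts take the sign alone. In group 10 the log2 fold changes were -0.086 ± 0.139 (SE) for Hoxa10, -0.196 ± 0.155 for Hoxc10 and -0.571 ± 1.34 for Hoxd10. Trained replicate 2 had the highest value of all libraries in each of these 3 genes. Hoxd10 was at 0.620, 9.70 and 0.372 CPM in trained replicates 1, 2 and 3 and at 2.95, 7.69 and 4.79 CPM in the untrained ones.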
